A study of Homo sapiens with 34 samples.

How the data were processed

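The data were bulk RNA-seq gene counts of subcutaneous adipose biopsies, 34 libraries from 9 participants with obesity and lipedema. Abdominal (SAAT) and femoral (SFAT) tissue was taken before and after a weight loss of 9%, and 8 participants had libraries from both visits. Per the labels' protocols, total RNA was extracted with QIAzol and RNeasy kits and sequenced on a NovaSeq instrument in a single run. The deposited values are whole-number counts per gene, which the authors made with STAR 2.5.2b and featureCounts 2.0.6 on GRCh38, per the submitters' processing notes. The annotation release, the strandedness of the counting and the treatment of multi-mapping reads are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be told apart. The table was not normalized, and its 34 columns were each matched to 1 sample by name. It held 62754 genes, of which 1 had no values and was left out. Symbols were found for 42342 gene identifiers. Coordinates, 1-based, came from GENCODE 29 on GRCh38 (58260 of the identifiers are in it), which need not be the release used for counting. Of the 95 genes named with fold changes, 2 shared at least 20% of their exon bases with another gene on the same strand and 4 with a gene on the opposite strand. Those on the same strand were TM4SF19 (42.9%) and COX8A (34.5%).

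Each comparison of 2 groups used the counts of those groups in R 4.3.3 with edgeR 4.0.16: filterByExpr (minimum count 10, minimum total 15), TMM scaling, glmQLFit with robust estimation and glmQLFTest, with the participant as block. Whether the weight-loss change differed between depots was fitted over the 32 libraries of participants with both visits, with terms for participant, participant by depot and participant by visit. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. A rise, fall or call refers to this test. Standard errors came from the fitted fold change and its quasi-likelihood F statistic, CPM from TMM-scaled library sizes, and log2 CPM used a prior count of 2.

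The 37 gene lists (cell types, pathways, patterning genes) were set before the data were examined. Each list was tested with camera at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, which asks if the genes of a list move without a comparison with other genes, all with Benjamini-Hochberg adjustment over the lists of a comparison. The mean log2 CPM difference of a list per participant was tested with an exact sign-flip permutation test, which with 8 pairs cannot give a p under 0.0078. Counts of members called are given over all genes and adjusted over the list alone.

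Pairing came from the labels, which name the participant of each biopsy. As a check, the deviations of libraries from their group means were correlated. For libraries of the same participant the median was 0.339 for the depots before weight loss (smallest 0.138), 0.285 for the depots after it (0.0838), 0.361 for the visits in SAAT (0.184) and 0.335 for the visits in SFAT (0.0835). For libraries of different participants it was -0.0380, -0.0392, -0.0451 and -0.0369. The best match was the participant's own library for 8 of 9, 8 of 8, 8 of 8 and 8 of 8 pairs.

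The genes named were taken by a rule set before the data were examined. The first part takes the 10 largest rises and 10 largest falls among called genes with a symbol, a mean log2 CPM of at least 1 and the same sign in all but at most 1 pair. The next part takes the 2 members of each list with the smallest p among those called, or the member with the smallest p, with values only, where none was called. The last part takes 15 fixed genes, LEP, ADIPOQ, CD68, TREM2, COL6A3, LYVE1, PROX1, HOTAIR, HOXC10, SHOX2, TBX5, FASN, SCD, ELOVL6 and UCP1, whatever their p. For the interaction it takes the 5 genes of smallest p in each direction among those called. Not every gene of the rule is printed, and 1 called gene is not reported here. XIST, Y-linked genes and, in the first part, variable segments of immunoglobulins and T cell receptors were left out.

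The steps were tested on simulated counts with the real means, library sizes and pairs and 200 genes changed. Each gene was drawn independently of the others, and the changed genes were taken from those above a minimum mean count. At folds of 1.25, 1.5 and 2, edgeR recovered 19.4%, 62.7% and 86.4%, with 3.91% of calls false over 19953 genes for the depots before weight loss. For the depots after it the values were 19.4%, 67.2% and 81.8%, with 9.70% of calls false over 19809 genes. Weight loss in SAAT gave 26.9%, 74.6% and 86.4%, with 4.26% of calls false over 19956 genes, weight loss in SFAT 20.9%, 67.2% and 80.3%, with 8.66% of calls false over 20077 genes. The interaction gave 10.4%, 61.2% and 68.2%, with 4.04% of calls false over 21868 genes. DESeq2 had 12.2%, 12.3%, 11.0%, 14.7% and 5.56% of its calls false in the same simulations. A list shifted by 1.25-fold was found in all 5 simulations, with the preset and with the estimated correlation. At the preset correlation 1 of 36 unshifted lists was called for weight loss in SAAT and 2 for the interaction. As simulated genes did not move together, these runs cannot show how often camera at the preset correlation calls lists of correlated genes.

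Alternatives were limma 3.58.1 (voom, and voom with quality weights), DESeq2 1.42.0, DESeq2's size factors, upper-quartile scaling, no filter on low counts, a mean CPM of at least 1, robust=FALSE, no participant block, all 34 libraries in 1 fit, the participants with both visits, each participant left out and, chosen after seeing the data, leaving out the libraries of under 5 M counts with their partners. Depot or visit labels were also swapped at random within participants, 100 draws per comparison and 40 for the interaction. Library totals ran from 0.913 to 36.2 M counts, and genes below the filter in the shallowest libraries were measured with little precision. Variants, genotypes and sample-level identities were left out. Figures were drawn with matplotlib 3.10.9.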

Results

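Subcutaneous adipose tissue was sampled by biopsy from 9 participants with obesity and lipedema, a disorder of painful, disproportionate fat on the legs and often the arms. Bulk RNA sequencing was done on abdominal tissue (SAAT) and femoral, or thigh, tissue (SFAT), before and after a weight loss of 9%. The 34 libraries comprised 9 SAAT and 9 SFAT libraries before weight loss and 8 of each depot after it, since 1 participant had samples from the first visit only. The median library held 22.0 M counts in SAAT before weight loss (range 3.87 to 27.4), 23.4 M in SFAT before (8.26 to 27.4), 23.8 M in SAAT after (2.83 to 36.2) and 19.3 M in SFAT after (0.913 to 26.9). In 3 libraries, the shallow ones, the total lay under 5 M counts. Gene levels are given as CPM (counts per M counts of scaled library size), mean ± SD over participants, and fold changes as log2 values ± standard error (SE) from the paired edgeR fit.

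The first comparison asked how thigh and abdominal fat differed within the same participant before weight loss. Large differences lay in genes that mark position along the body. HOXC12, a posterior homeobox gene on chromosome 12, 53954834 to 53958956 (GRCh38), averaged 6.88 ± 1.99 CPM in SFAT and 0.258 ± 0.304 CPM in SAAT (SD, n = 9), a log2 fold change of 4.74 ± 0.39 (edgeR adjusted p = 3.8e-05). HOTAIR, the long noncoding RNA of the same HOXC cluster (chromosome 12, 53962308 to 53974956), averaged 2.68 ± 1.26 CPM in SFAT and 0.118 ± 0.126 CPM in SAAT, with a log2 fold change of 4.32 ± 0.45 (edgeR adjusted p = 6.8e-05). HOXA5, an anterior homeobox gene on chromosome 7, 27141052 to 27143668, ran the other way at 5.18 ± 1.33 CPM in SFAT and 25.5 ± 3.09 CPM in SAAT, a log2 fold change of -2.30 ± 0.10 (edgeR adjusted p = 1.9e-09). Each of these 3 differences had the same sign in 9 of 9 pairs.

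In all, edgeR's quasi-likelihood test with the participant as block called 1604 of 20524 genes at a Benjamini-Hochberg adjusted p under 0.05, 888 higher and 716 lower in SFAT, and 209 of them differed by at least 2-fold. Among called genes with a symbol, a mean log2 CPM of at least 1 and the same sign in all but at most 1 pair, HOXC12 rose most in SFAT. It was followed by KRT16, a keratin of stressed epithelium (log2 fold change 2.42 ± 0.43), COMP, a cartilage matrix protein (2.35 ± 0.47), the posterior gene HOXA13 (2.11 ± 0.27) and SCUBE1, a secreted EGF-domain protein (2.03 ± 0.36). The largest falls were in the netrin receptor UNC5C on chromosome 4, 95162504 to 95549206 (-2.52 ± 0.13), HOXA5, HOXA6 (-2.03 ± 0.11), the lipoprotein gene APOB (-1.98 ± 0.20) and HOXA3 (-1.93 ± 0.10). Among fixed genes of interest, the limb regulator SHOX2 rose in SFAT (1.52 ± 0.22, edgeR adjusted p = 0.0014), HOXC10 rose (0.93 ± 0.13) and TBX5, a regulator of the forelimb field and of heart development, fell (-1.90 ± 0.37, edgeR adjusted p = 0.0176). The leptin gene LEP averaged 1920 ± 339 CPM in SFAT and 1613 ± 338 CPM in SAAT, a fold of 1.20 (edgeR adjusted p = 0.0153), whereas for adiponectin, ADIPOQ, the log2 fold change was -0.11 ± 0.07 (edgeR adjusted p = 0.442).

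Of the 31 measured HOX cluster genes, 6 were higher and 15 lower in SFAT (6 and 18 adjusted over the list alone). The list as a whole ranked lower in SFAT (camera adjusted p = 2.4e-12), and it was the 1 list whose call held with a correlation estimated from the data (adjusted p = 0.026). The higher members included HOXC12 and HOXA13, the lower ones HOXA5 and HOXA3. In the list of limb and trunk patterning regulators, 6 of 24 were higher and 8 lower (7 and 11 adjusted over the list alone). Among them were HOTAIR and, in the other direction, IRX2 (-1.06 ± 0.12), with no call for the list (camera adjusted p = 0.253; its median log2 fold change was -0.21 and its mean 0.03).

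Macrophage genes were higher in SFAT, with 11 of 29 called higher (23 adjusted over the list alone). The lipopolysaccharide co-receptor CD14 averaged 61.2 ± 15.6 CPM in SFAT and 41.1 ± 10.6 CPM in SAAT, a fold of 1.49 (edgeR adjusted p = 8.8e-04), and MS4A7 78.3 ± 19.3 CPM in SFAT and 56.0 ± 8.28 CPM in SAAT (edgeR adjusted p = 0.0023). The mean log2 difference over the list was 0.53 ± 0.36 (SD, n = 9) and was above 0 in 9 of 9 participants (exact sign-flip permutation test, two-sided, adjusted p = 0.0289). The camera test called the list (adjusted p = 6.8e-17), but not with an estimated correlation (adjusted p = 0.292). Of the lipid-associated macrophage genes 6 of 24 were higher (16 adjusted over the list alone). They included the lipid droplet gene PLIN2 (0.72 ± 0.09), which adipocytes also express, and TM4SF19 (1.47 ± 0.34), while TREM2 reached 0.98 ± 0.30 (edgeR adjusted p = 0.0716). Of the exon bases of TM4SF19, 42.9% lie in exons of other genes on the same strand. The list had a camera adjusted p of 4.0e-14 (adjusted p = 0.292 with an estimated correlation). The list of dendritic cells and antigen presentation had 6 of 16 genes higher (10 adjusted over the list alone), such as HLA-DRA at 0.46 ± 0.08 (camera adjusted p = 1.8e-06, and adjusted p = 0.292 with an estimated correlation). Lists of other blood-derived cells were called higher by camera as well, at an adjusted p of 2.0e-05 for T and NK cells, 0.0058 for B and plasma cells and 0.0011 for neutrophils (adjusted p = 0.472, 0.357 and 0.49 with an estimated correlation). Their mean log2 differences were 0.46 ± 0.57, 0.45 ± 0.56 and 0.82 ± 1.31 (SD, n = 9), above 0 in 8, 8 and 5 of 9 participants. Genes of the mitochondrial genome took 4.42 ± 3.05% of counts in SFAT and 2.88 ± 0.732% in SAAT (exact sign-flip permutation test, p = 0.191), and 1 SFAT library far above the others carried much of that gap. As a list they had a camera adjusted p of 0.0034 (adjusted p = 0.515 with an estimated correlation, and a camera adjusted p of 0.0505 without the shallow pair, a fit chosen after seeing the data), and the red blood cell list one of 0.253.

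Metabolic lists split by direction. Of 37 nuclear genes of oxidative phosphorylation, 8 were higher in SFAT (17 adjusted over the list alone). The cytochrome c oxidase subunits COX5B (0.31 ± 0.06) and COX4I1 (0.29 ± 0.06) had the smallest p, and the list mean was above 0 in 9 of 9 participants. Genes of lipolysis and its hormonal control were lower, 5 of 20 (6 adjusted over the list alone, with 1 higher), led by the natriuretic peptide receptor NPR1 (-0.65 ± 0.06) and the lactate receptor HCAR1 (-0.70 ± 0.10). Insulin signalling had 5 of 20 genes lower (8 adjusted over the list alone), with the glucose transporter SLC2A4 at -0.45 ± 0.09 and IRS2 at -0.29 ± 0.07. Camera called these 3 lists (adjusted p = 6.6e-09, 9.6e-06 and 0.0016), none of them with an estimated correlation (adjusted p = 0.292, 0.292 and 0.292). Fatty acid and triglyceride synthesis went both ways, 2 higher and 3 lower of 24 (3 and 5 adjusted over the list alone). The desaturase SCD averaged 16767 ± 4780 CPM in SFAT and 10120 ± 6060 CPM in SAAT (edgeR adjusted p = 0.0209), whereas ACACB fell (-0.39 ± 0.06) and FASN gave -0.33 ± 0.10 (edgeR adjusted p = 0.0599). Adipocyte identity genes also went both ways, 4 higher, such as RBP4 (0.77 ± 0.10), and 3 lower, such as TRARG1 (-0.39 ± 0.07), of 24 (4 and 5 adjusted over the list alone).

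Extracellular matrix genes were higher for 10 and lower for 3 of 48 (16 and 3 adjusted over the list alone; camera adjusted p = 6.6e-05, and adjusted p = 0.292 with an estimated correlation). Elastin, ELN, was lower (-0.64 ± 0.09), TGFBI higher (0.53 ± 0.10) and the collagen COL6A3 gave 0.17 ± 0.07 (edgeR adjusted p = 0.163). In the blood endothelium list 2 of 24 genes fell (4 adjusted over the list alone, and 5 over all genes without the shallow pair, a fit chosen after seeing the data): GPIHBP1, which anchors lipoprotein lipase on capillaries (-0.43 ± 0.07), and SOX17 (-0.61 ± 0.14), at a camera adjusted p of 4.3e-06 (adjusted p = 0.456 with an estimated correlation). Lymphatic genes went both ways, 4 higher and 3 lower of 17 (5 and 4 adjusted over the list alone), with no call for the list (camera adjusted p = 0.729). The growth factor VEGFC (-0.69 ± 0.11) and its cofactor CCBE1 (-0.60 ± 0.09) were lower, and LYVE1, which tissue macrophages also carry, was higher (0.63 ± 0.15). The lymphatic regulator PROX1 gave 0.23 ± 0.19 (edgeR adjusted p = 0.539). Aromatase, CYP19A1, the enzyme that forms estrogens, averaged 5.56 ± 2.66 CPM in SFAT and 1.89 ± 1.07 CPM in SAAT, a fold of 3.01 (edgeR adjusted p = 6.3e-05), and the glucocorticoid-responsive FKBP5 was lower (-0.44 ± 0.09). Near the threshold, camera placed mast cells higher (adjusted p = 0.0337) and smooth muscle and pericytes lower (adjusted p = 0.0477). Both were lost with an estimated correlation (adjusted p = 0.514 and 0.508) and by camera without the shallow pair (adjusted p = 0.0575 and 0.0806). Fatty acid oxidation and branched-chain amino acid breakdown passed in the fit without that pair alone (camera adjusted p = 0.0162 and 0.0239).

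With a participant left out, these genes kept their call in fewer than 9 of 9 edgeR fits: TM4SF19 in 8 (1.28 to 1.72), SCD in 7 (0.79 to 1.07) and LYVE1 in 2 (0.54 to 0.74), with the range of log2 fold changes over the fits in brackets. Without the participant as a block the same libraries gave 165 calls in place of 1604, and without participant 9 the paired fit gave 945. In simulated counts for this comparison the edgeR fit recovered 19.4% of genes changed by 1.25-fold, 62.7% at 1.5-fold and 86.4% at 2-fold. Most differences of 1.25-fold were thus below what 9 pairs detect.

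**Figure D1:**
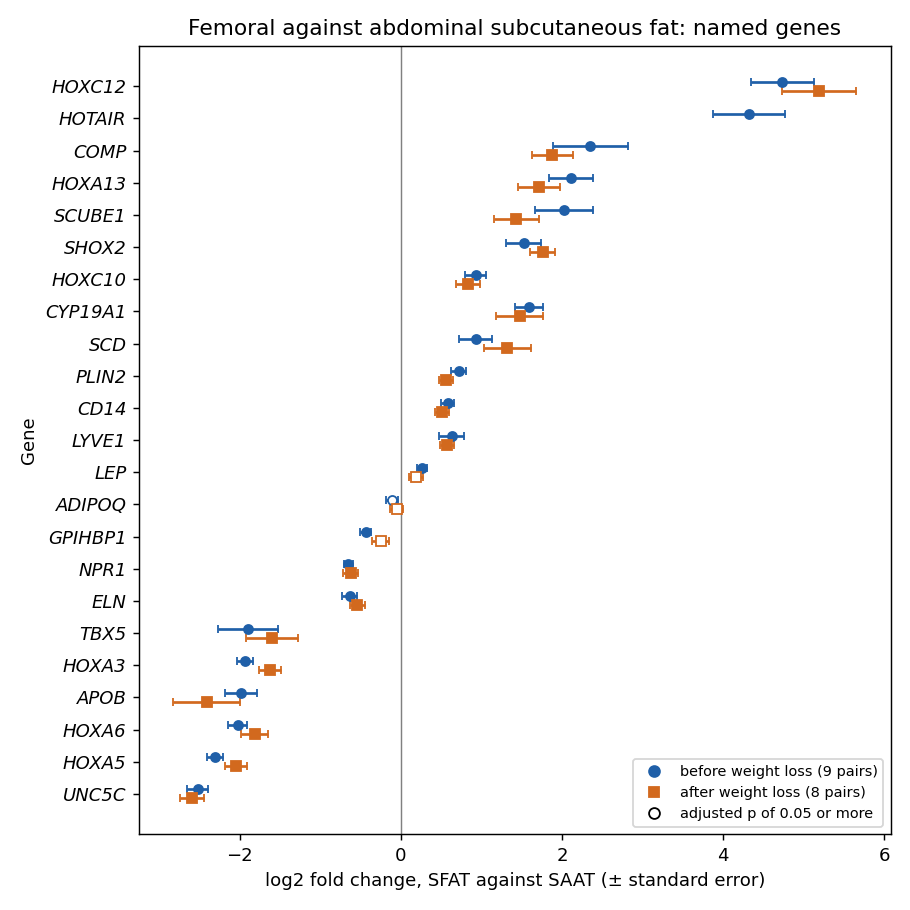
Log2 fold change of SFAT against SAAT (x axis, error bars 1 SE) for a selection of the named genes (y axis) before weight loss (circles, 9 pairs) and after it (squares, 8 pairs); open symbols mark an adjusted p of 0.05 or more. Among those drawn, HOXC12 stands farthest to the right (4.74 before, 5.19 after) and UNC5C farthest to the left (-2.52 and -2.59). HOTAIR did not pass the count filter after weight loss and has no square. It then averaged 2.99 ± 1.93 CPM in SFAT and 0.0252 ± 0.0444 CPM in SAAT (SD, n = 8), a difference that was not tested.

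**Figure D2:**
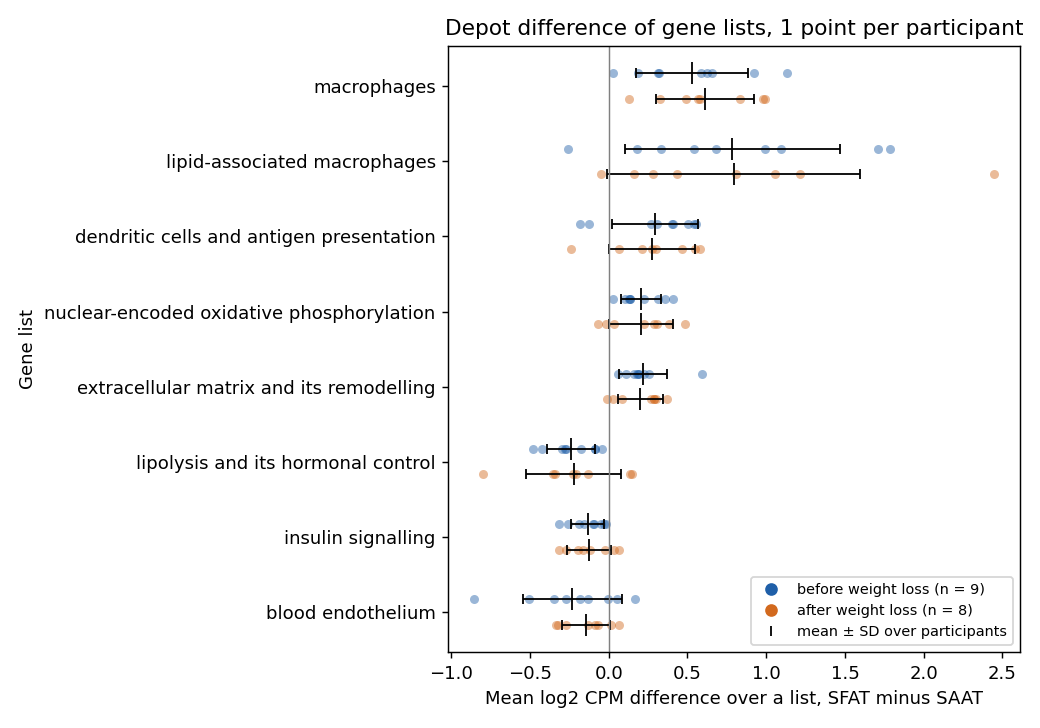
Mean log2 CPM difference, SFAT minus SAAT, over the measured genes of 8 gene lists, with 1 point per participant and the mean ± SD as black bars, before (n = 9) and after weight loss (n = 8). Macrophage genes lie above 0 in 9 of 9 participants before and 8 of 8 after.

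The same question after weight loss, in 8 pairs, gave a similar picture. HOXC12 averaged 6.33 ± 2.53 CPM in SFAT and 0.200 ± 0.307 CPM in SAAT (SD, n = 8; log2 fold change 5.19 ± 0.46, edgeR adjusted p = 2.2e-05), SHOX2 11.0 ± 1.77 CPM in SFAT and 3.32 ± 0.937 CPM in SAAT (edgeR adjusted p = 4.4e-06), and HOXA5 5.41 ± 1.72 CPM in SFAT and 21.8 ± 3.43 CPM in SAAT (edgeR adjusted p = 1.8e-07). Macrophage genes were again higher in SFAT, 21 of 29 (25 adjusted over the list alone). The scavenger receptor MARCO averaged 9.73 ± 6.08 CPM in SFAT and 4.08 ± 2.77 CPM in SAAT, a fold of 2.56 (edgeR adjusted p = 1.2e-04), and the complement gene C1QC 112 ± 33.7 CPM in SFAT and 76.5 ± 26.2 CPM in SAAT, a fold of 1.49 (edgeR adjusted p = 2.3e-04).

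Here 1413 of 20411 genes were called, 784 higher and 629 lower in SFAT, 254 of them by at least 2-fold. By the same rule HOXC12 rose most, followed by RN7SL471P, a 7SL RNA pseudogene whose reads near-identical copies could share (log2 fold change 2.26 ± 0.28), the heparan sulfate sulfotransferase HS3ST2 (2.01 ± 0.23), COMP (1.88 ± 0.25) and SHOX2 (1.76 ± 0.15). The largest falls were in NWD2 (-3.01 ± 0.50), UNC5C (-2.59 ± 0.15), the transcription factor DMRT3 (-2.50 ± 0.31), APOB (-2.41 ± 0.41) and HOXA5 (-2.05 ± 0.14). HOXC10 (0.84 ± 0.15), SCD (1.32 ± 0.29) and LYVE1 (0.57 ± 0.08) were higher and TBX5 lower (-1.60 ± 0.33). LEP gave 0.19 ± 0.09 (edgeR adjusted p = 0.226), FASN -0.26 ± 0.13, COL6A3 0.09 ± 0.08 and ADIPOQ -0.05 ± 0.08, none of them past the threshold.

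The macrophage list mean was 0.61 ± 0.31 (SD, n = 8) and above 0 in 8 of 8 participants (exact sign-flip permutation test, p = 0.0078, the smallest that 8 pairs allow, adjusted p = 0.145 over the 37 lists). Its camera call (adjusted p = 1.4e-31) was lost with an estimated correlation (adjusted p = 0.163). Lipid-associated macrophage genes were higher for 9 of 24 (13 adjusted over the list alone; camera adjusted p = 1.3e-16, and adjusted p = 0.271 with an estimated correlation). Among them were PLIN2 (0.56 ± 0.09), GPNMB (0.72 ± 0.12) and TREM2, which averaged 11.7 ± 7.04 CPM in SFAT and 4.20 ± 3.59 CPM in SAAT (edgeR adjusted p = 0.0154). In the T and NK cell list CD4, which macrophages also carry, was the 1 gene called (0.59 ± 0.09; camera adjusted p for the list = 0.0188, and adjusted p = 0.454 with an estimated correlation). The neutrophil list had a mean log2 difference of 0.63 ± 1.02 (SD, n = 8; camera adjusted p = 0.002, and adjusted p = 0.459 with an estimated correlation). Red blood cell genes, 3 of them measured, had a list mean of 1.61 ± 1.70 (SD, n = 8), above 0 in 7 of 8 participants (exact sign-flip permutation test, p = 0.0234, adjusted p = 0.145 over the 37 lists; camera adjusted p = 0.0214, and adjusted p = 0.365 with an estimated correlation). The haemoglobin genes HBA1 and HBA2 had a median of 0 counts in each group, so this list is a weak gauge of blood. Genes of the mitochondrial genome ranked higher by camera as well (adjusted p = 0.0035, and adjusted p = 0.602 with an estimated correlation). Immediate early genes, which respond within minutes to stimulation and to tissue handling, moved with the immune lists. Of these 4 of 23 were higher in SFAT (5 adjusted over the list alone), such as EGR2 (1.31 ± 0.25) and EGR1 (0.75 ± 0.16), at a camera adjusted p of 2.8e-05 (adjusted p = 0.271 with an estimated correlation). Before weight loss the same list gave a camera adjusted p of 0.002 (adjusted p = 0.514 with an estimated correlation). Fits without the shallow libraries and their partners were chosen after seeing the data. In these the immediate early list missed the threshold before weight loss (camera adjusted p = 0.0806) and had 2 genes called higher after it, and the T and NK cell list and the mitochondrial genome missed it after weight loss (camera adjusted p = 0.0653 and 0.119). The red blood cell list kept its call there (camera adjusted p = 0.0364). After weight loss, too, the SFAT partner of the shallow SAAT library had the highest mitochondrial share of its group, 5.03% of counts. These fits thus do not isolate depth.

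Oxidative phosphorylation genes were higher for 6 of 37 (14 adjusted over the list alone), such as NDUFB5 (0.34 ± 0.07) and COX8A (0.47 ± 0.10). Lipolysis genes were lower for 5 of 19 (8 adjusted over the list alone, with 1 higher), such as NPR1 (-0.63 ± 0.09) and the prostaglandin receptor PTGER3 (-0.38 ± 0.07). Matrix genes were higher for 14 and lower for 3 of 48 (18 and 5 adjusted over the list alone, and 8 higher over all genes without the shallow pairs), led by the matricellular growth factor gene CCN2 (1.08 ± 0.10) and the collagen crosslinker LOXL4 (0.63 ± 0.09). Blood endothelium genes were lower for 3 of 24 (3 adjusted over the list alone), among them EMCN (-0.25 ± 0.06) and FLT1 (-0.29 ± 0.08). In the smooth muscle and pericyte list 2 of 19 were lower (2 adjusted over the list alone), such as the potassium channel genes ABCC9 (-0.65 ± 0.07) and KCNJ8 (-0.79 ± 0.09). HOX cluster genes were higher for 4 and lower for 11 of 31 (6 and 19 adjusted over the list alone). Camera gave an adjusted p of 7.7e-08 for oxidative phosphorylation, 7.8e-04 for lipolysis, 1.2e-05 for matrix, 0.0014 for blood endothelium and 3.5e-06 for HOX genes. With an estimated correlation these were 0.359, 0.394, 0.271, 0.271 and 0.271, and no list was called. Camera also placed dendritic cells (6.1e-08), cytokines (9.2e-05), cell division (3.7e-04) and ribosomal proteins (0.0304) higher and insulin signalling (0.0094) lower, with the adjusted p in brackets. With an estimated correlation their adjusted p was 0.271, 0.309, 0.394, 0.681 and 0.451, and without the shallow pairs ribosomal proteins missed the camera threshold (adjusted p = 0.394). Cholesterol synthesis (0.0158), interferon-stimulated genes (0.041), smooth muscle and pericytes (0.041) and skeletal muscle (0.0376) passed it in that fit alone, with the camera adjusted p in brackets. With a participant left out, these genes kept their call in fewer than 8 of 8 edgeR fits: EMCN in 4 (-0.28 to -0.21), FLT1 in 3 (-0.33 to -0.23), TREM2 in 7 (1.32 to 1.81), TBX5 in 5 (-1.77 to -1.35) and SCD in 2 (1.16 to 1.51), with the range of log2 fold changes over the fits in brackets. Without the block 282 genes were called, and without participant 3, 4 or 5 the paired fit called 862, 608 and 856 in place of 1413.

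The depot difference was shared between visits. Of 20062 genes tested at both, 847 were called at both with the same sign (461 higher and 386 lower in SFAT), against 56.3 for independent lists, and 0 with opposite signs. Of the 1591 called before weight loss, 1575 had the same sign after it. Across all genes, which are not independent replicates, the fold changes correlated at Pearson r = 0.72, and across those called before at 0.95. The visits shared participants but no libraries.

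**Figure D3:**
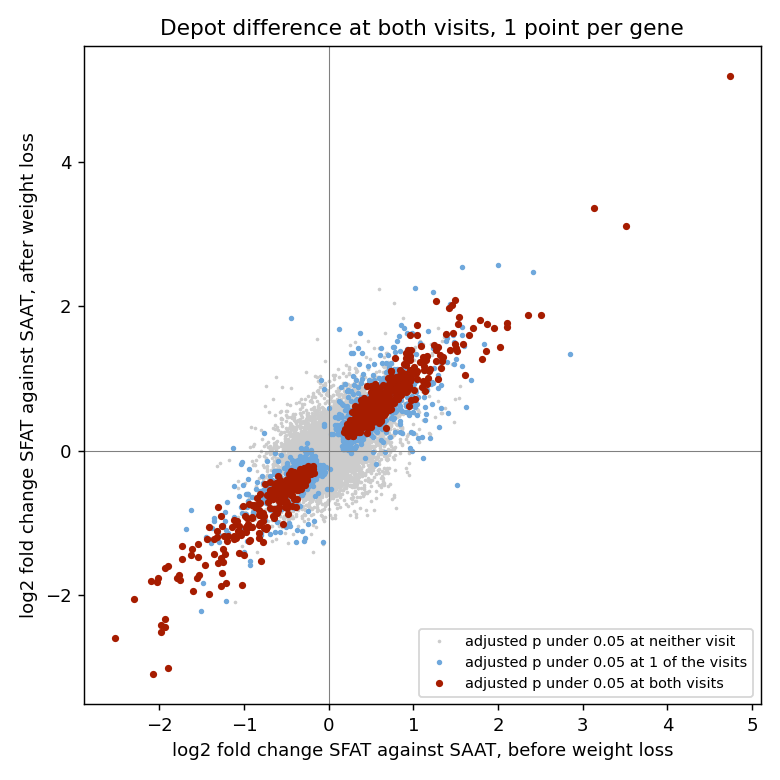
Log2 fold change of SFAT against SAAT before weight loss (x axis) and after it (y axis), with 1 point per gene tested at both visits, coloured by whether the adjusted p was under 0.05 at neither, 1 or both. The 847 genes called at both visits lie at the lower left or upper right.

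In abdominal fat few genes were called after weight loss. FADS2, the desaturase that starts the synthesis of long polyunsaturated fatty acids (chromosome 11, 61792980 to 61867354), fell from 117 ± 78.4 CPM before to 67.3 ± 51.0 CPM after weight loss (SD, n = 8), a log2 fold change of -0.84 ± 0.10 in 8 of 8 pairs (edgeR adjusted p = 0.0303). It was the 1 gene called of 20475, with 1576 at an unadjusted p under 0.05 against 1024 by chance. In simulated counts for this comparison edgeR recovered 26.9% of genes changed by 1.25-fold, so few calls do not mean few changes. Limma-voom called 1 and DESeq2 99 (45 higher, 54 lower). The fit without the participant as a block called 0. Leaving out participants 1, 2, 3, 4, 5, 6, 8 and 9 in turn gave 0, 1, 1, 0, 5, 2, 0 and 3. The call without participant 3 was another gene. FADS2 missed the threshold without participant 1, 3, 4 or 8, at log2 fold changes between -0.91 and -0.77 over all participants left out.

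As a group, genes of fatty acid and triglyceride synthesis ranked lower by camera after weight loss in SAAT, with a call that the choice of correlation decided (adjusted p = 2.9e-17 at the preset and 0.243 with an estimated correlation). Over all genes 1 of 24 was called, and 11 were lower adjusted over the list alone, with 0 higher. Without the shallow pair, a fit chosen after seeing the data, 7 were lower adjusted over the list alone. The 11 included SCD, at 10874 ± 6010 CPM before and 5767 ± 3712 CPM after weight loss (log2 fold change -1.08 ± 0.25, lower in 8 of 8 pairs, edgeR adjusted p = 0.302 over all genes and 0.0174 over the list), and FASN, the fatty acid synthase, at -0.38 ± 0.13, while ELOVL6 gave -0.41 ± 0.34. The list mean was -0.28 ± 0.24 (SD, n = 8) and below 0 in 7 of 8 participants (exact sign-flip permutation test, p = 0.0234, adjusted p = 0.347). In cholesterol synthesis and uptake no gene was called over all genes by edgeR, and 2 of 24 were lower adjusted over the list alone (4 without the shallow pair), among them the sterol sensor INSIG1 (-0.43 ± 0.08; camera adjusted p = 1.9e-07, and adjusted p = 0.243 with an estimated correlation). Camera also placed adipocyte identity (adjusted p = 9.8e-05), lipolysis (adjusted p = 9.8e-05), nuclear genes of oxidative phosphorylation (adjusted p = 1.3e-05) and fatty acid oxidation (adjusted p = 0.0113, and 0.139 without the shallow pair) lower. With an estimated correlation these had an adjusted p of 0.683, 0.517, 0.517 and 0.683. It placed blood endothelium (adjusted p = 0.0012) and interferon-stimulated genes (adjusted p = 0.0016) higher, neither with an estimated correlation (adjusted p = 0.694 and 0.738). T and NK cells passed in the fit without the shallow pair alone (camera adjusted p = 0.0068). The neutrophil and red blood cell lists, at a camera adjusted p of 0.004 and 0.003, ranked lower (adjusted p = 0.701 and 0.517 with an estimated correlation). Values of other genes that missed the threshold were -0.52 ± 0.10 for the adrenergic receptor ADRB1, -0.39 ± 0.09 for the matrix gene SPARC, -0.20 ± 0.07 for PLIN4, -0.31 ± 0.12 for LEP, -0.06 ± 0.08 for ADIPOQ, 0.26 ± 0.08 for the macrophage gene CD163 and -0.09 ± 0.27 for TREM2.

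In femoral fat 11 of 20516 genes passed the threshold after weight loss, 2 higher and 9 lower, with 1743 at an unadjusted p under 0.05 against 1026 by chance. The cannabinoid receptor CNR1 rose (13.1 ± 3.34 CPM before and 20.2 ± 6.62 CPM after weight loss, edgeR adjusted p = 0.0146), as did the intermediate filament gene NES (0.45 ± 0.07). FADS2 fell again (80.5 ± 50.1 CPM before and 45.3 ± 30.2 CPM after weight loss, edgeR adjusted p = 0.0142). The glutamate receptor subunit GRIN2B fell (-0.57 ± 0.06, edgeR adjusted p = 0.0013), and so did the mitochondrial creatine kinase CKMT2 (-0.56 ± 0.09). Falls were also seen in UCHL1 (-0.40 ± 0.07), the endopeptidase MME (-0.34 ± 0.06), the progenitor marker SEMA3C (-0.32 ± 0.05), ECHDC1 (-0.31 ± 0.05) and the lipid phosphatase PLPP1 (-0.30 ± 0.05).

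Fatty acid and triglyceride synthesis had 1 of 24 genes called, and 10 lower with 0 higher adjusted over the list alone. SCD gave -0.64 ± 0.15 (edgeR adjusted p = 0.197), lower in 8 of 8 pairs, FASN -0.29 ± 0.09 and ELOVL6 -0.52 ± 0.24. The list mean was -0.23 ± 0.18 (SD, n = 8), below 0 in 7 of 8 participants (exact sign-flip permutation test, p = 0.0156, adjusted p = 0.193), at a camera adjusted p of 7.2e-14 (adjusted p = 0.251 with an estimated correlation). Of the blood endothelium genes none was called over all genes by edgeR, and 9 of 24 were higher adjusted over the list alone, such as the venular receptor ACKR1 (0.41 ± 0.09, edgeR adjusted p = 0.113 over all genes and 0.0062 over the list; camera adjusted p = 7.2e-14, and adjusted p = 0.399 with an estimated correlation). Branched-chain amino acid breakdown was lower (camera adjusted p = 0.0023, and adjusted p = 0.251 with an estimated correlation). Its list mean was below 0 in 8 of 8 participants, and it was the 1 list called by fry (adjusted p = 0.0376). By the exact sign-flip permutation test none of the 37 lists passed after adjustment. Other lists that camera placed lower, with the adjusted p in brackets, were adipocyte identity (3.5e-05), cholesterol synthesis (0.002), lipolysis (0.004), nuclear genes of oxidative phosphorylation (5.4e-05), fatty acid oxidation (0.002), the mitochondrial genome (1.6e-05), matrix (0.035), T and NK cells (3.3e-04), B and plasma cells (0.0292), neutrophils (0.0032) and skeletal muscle (0.0448). With an estimated correlation the camera adjusted p of these was 0.422, 0.255, 0.422, 0.422, 0.422, 0.556, 0.611, 0.588, 0.588, 0.588 and 0.422. Camera placed macrophages (0.0079), mast cells (0.03) and interferon-stimulated genes (5.7e-04) higher (adjusted p in brackets), at an adjusted p of 0.588, 0.588 and 0.615 with an estimated correlation. Without the shallow pair, a fit chosen after seeing the data, matrix and skeletal muscle missed the threshold (camera adjusted p = 0.0777 and 0.0683). In that fit camera newly called lipid-associated macrophages (adjusted p = 0.0057), dendritic cells (0.039), red blood cells (0.0188), cell division (0.039) and ribosomal proteins (0.0338), so its lists rose from 17 to 20. LEP gave -0.39 ± 0.10 (edgeR adjusted p = 0.182), lower in 8 of 8 pairs, SFRP2 -0.70 ± 0.12, ADIPOQ -0.01 ± 0.08 and TREM2 0.56 ± 0.47. Limma-voom called 6 genes, DESeq2 194 (72 higher, 122 lower) and the fit without the participant as a block 0. Leaving out participants 1, 2, 3, 4, 5, 6, 8 and 9 in turn gave 2, 2, 5, 7, 6, 1, 9 and 4. Over these 8 edgeR fits GRIN2B was called in 8 and CNR1 in 5 (0.55 to 0.63), FADS2 in 5 (-0.91 to -0.75), NES in 1 (0.42 to 0.52), CKMT2 in 1 (-0.61 to -0.50), UCHL1 in 1 (-0.45 to -0.36), MME in 0 (-0.38 to -0.31), SEMA3C in 0 (-0.34 to -0.31), ECHDC1 in 0 (-0.33 to -0.28) and PLPP1 in 0 (-0.33 to -0.28), with the range of log2 fold changes in brackets.

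**Figure D4:**
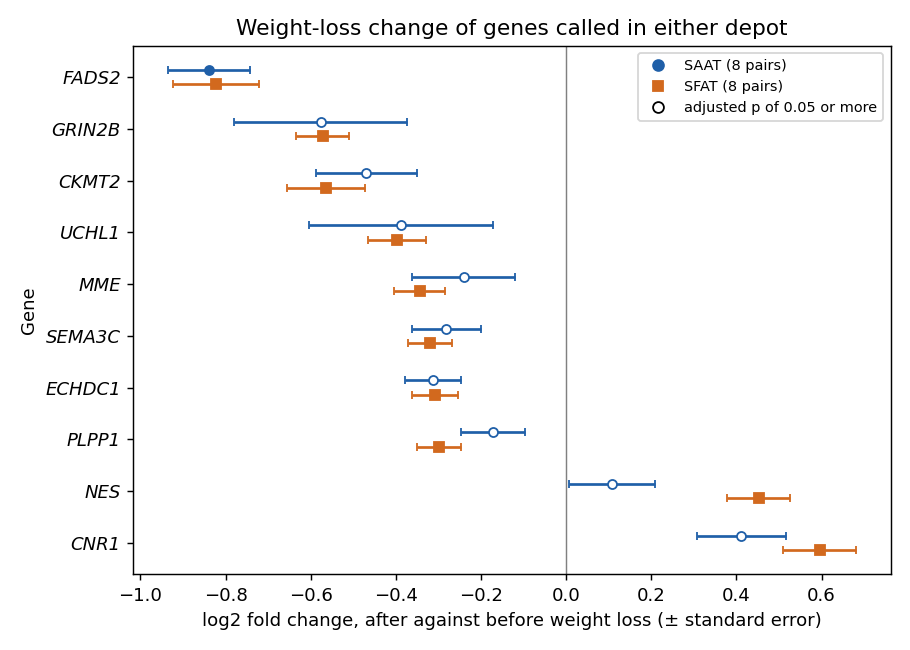
Log2 fold change after against before weight loss (x axis, error bars 1 SE) in SAAT (circles) and SFAT (squares), 8 pairs each, for named genes called in either depot (y axis); filled symbols mark an adjusted p under 0.05. FADS2 lies at -0.84 in SAAT and -0.82 in SFAT.

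Whether the weight-loss change differed between depots was tested directly as an interaction. No gene of 22194 was called by edgeR (0, with 678 at an unadjusted p under 0.05 against 1110 by chance), by limma-voom (0) or by DESeq2 (0). The 11 genes called in SFAT all had the same sign in SAAT, where CNR1 gave 0.41 ± 0.10 and NES 0.11 ± 0.10. Across 19953 genes, which are not independent replicates, the weight-loss changes of the depots correlated at Pearson r = 0.27. The overlap of calls was FADS2 alone (1 gene). By camera, 3 of the 37 lists passed, blood endothelium (adjusted p = 1.7e-04), cell division (0.0033) and red blood cells (0.036), each with the higher change in SFAT and each at an adjusted p of 0.965 with an estimated correlation. In simulated interaction counts, with genes drawn independently, camera at the preset correlation called 2 of 36 unshifted lists. Without the shallow libraries and their partners, a fit chosen after seeing the data, camera called 8 lists in place of 3. Simulated counts for the interaction gave recovery of 10.4%, 61.2% and 68.2% of genes changed by 1.25-, 1.5- and 2-fold. The real fit had fewer small p-values than chance gives, for a reason not tested. This recovery may thus overstate what the real fit could detect.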

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

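The values here describe samples or pairs that stand apart, and no explanation of them was tested. In 184 groups of 8 or 9 values, 23 had a highest or lowest value whose gap to its neighbour, as a share of the whole range, passed Dixon's 95% limit, against 9.20 by chance, which singles out about 1 in 20 groups.

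For total counts, 1 library of each group lay far below the others, with a gap of 0.559 of the range in SAAT before weight loss, 0.746 in SFAT before, 0.562 in SAAT after and 0.562 in SFAT after. The share of counts from the mitochondrial genome was far above the others in 1 library of SFAT before (0.615), of SAAT after (0.704) and of SFAT after (0.680).

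Among the paired differences between depots before weight loss, 1 participant stood apart for the extracellular matrix and its remodelling list (highest, 0.632), NPR1 (highest, 0.511), SOX17 (lowest, 0.700), CYP19A1 (lowest, 0.496), HOXC10 (highest, 0.513) and ACADL (lowest, 0.645). Among the paired differences between depots after weight loss, 1 participant stood apart for RN7SL471P (lowest, 0.629), HS3ST2 (lowest, 0.743), LOXL4 (lowest, 0.559), EGR2 (lowest, 0.645) and TREM2 (highest, 0.543). Among the paired differences with weight loss in SAAT, 1 participant stood apart for the nuclear-encoded oxidative phosphorylation list (lowest, 0.561). Among the paired differences with weight loss in SFAT, 1 participant stood apart for the HOX cluster genes list (lowest, 0.672), the nuclear-encoded oxidative phosphorylation list (lowest, 0.734), the cholesterol synthesis and uptake list (lowest, 0.612) and SCD (lowest, 0.679).

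In the interaction test 3 lists passed by camera, and 8 without the shallow libraries and their partners, a fit chosen after seeing the data. Blood endothelium (camera adjusted p = 1.7e-04), cell division (0.00329) and red blood cells (0.0360) ranked higher for SFAT minus SAAT. With an estimated correlation each had an adjusted p of 0.965, and the exact sign-flip permutation test over 8 participants gave p = 0.281, 0.852 and 0.484. For blood endothelium the mean difference of the changes was 0.12 ± 0.28 (SD, n = 8), above 0 in 6 participants.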

How the results depend on the processing

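The fits without the shallow libraries (under 5 M counts) were chosen after the data were seen, all other settings before. For the depots before weight loss the 1604 calls became 2700 with no filter on low counts and 945 to 1811 with a participant left out, lowest without participant 9. They stayed within 1.5 times under the other settings besides pairing. For the depots after weight loss the 1413 became 2412 with voom quality weights, 2238 with DESeq2, 2167 with no filter and 608 to 1445 with a participant left out (862, 608 and 856 without 3, 4 and 5). For weight loss in SAAT the 1 became 99 with DESeq2, 372 with no filter, 0 with all libraries in 1 fit, 0 without the shallow libraries and 0 to 5 with a participant left out. For weight loss in SFAT the 11 became 6 with voom, 17 with quality weights, 194 with DESeq2, 404 with no filter, 6 at a mean CPM of at least 1 and 4 with robust=FALSE. They became 0 with all libraries in 1 fit, 4 without the shallow libraries and 1 to 9 with a participant left out. Without the participant as a block the counts were 165, 282, 0 and 0, and 0 for the interaction. The interaction stayed at 0 calls under each setting run, with each participant left out too. The fit without the block leaves participant differences in the spread. With no filter the median over genes of the prior degrees of freedom became infinite in the 4 paired fits (from 8.04, 10.7, 11.0 and 9.48). A large share of the genes thus took the common spread. Whether this raised the counts was not tested, nor was the cause of the other changed counts.

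Of the gene lists, camera called 18, 19, 10 and 17 in the paired comparisons and 3 in the interaction. With an estimated correlation these became 1, 0, 0, 0 and 0, and with fry 11, 11, 0, 1 and 0. Without the shallow libraries the interaction gave 8 lists by camera. Without the block camera called 18, 20, 10, 13 and 2. The overlap of depot calls between visits became 1359 at an adjusted p under 0.10. Of 2615 alternative values for 132 single-gene results, 2358 stayed on the same side of the threshold, 219 lost the call and 38 gained one. None of those called under either setting changed sign, while some genes below the threshold did. With totals under 5 M counts in 3 libraries, differences in low genes were not detectable there.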

Other observations

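The tests of adipocyte share, of blood and of overlapping gene models in this part were chosen after the results were seen. Single genes also differed between depots in further lists, some of which camera called and some not. Of the thermogenic genes (camera adjusted p = 0.117 before weight loss and 0.372 after it), 2 of 14 were higher in SFAT before weight loss and 3 of 15 after it. Adjusted over the list alone, 5 were higher and 2 lower before, and 3 higher after. The elongase ELOVL3 gave log2 fold changes of 1.32 ± 0.23 and 1.32 ± 0.24 (edgeR adjusted p = 0.0049 and 0.0033), and DIO2, which activates thyroid hormone, 0.91 ± 0.21 and 1.04 ± 0.18. The uncoupling protein gene UCP1 averaged at most 0.177 ± 0.236 CPM (SD, n = 9) in any group. In fatty acid oxidation (camera adjusted p = 0.0677 and 0.0775, and 0.0162 before weight loss without the shallow pair) ACAA2 was higher in SFAT (0.48 ± 0.07 and 0.44 ± 0.08) and ACADL lower (-0.52 ± 0.08 and -0.53 ± 0.09). Mast cell genes were higher in SFAT after weight loss for 3 of 11 (4 adjusted over the list alone, and 1 over all genes without the shallow pairs), led by the near-identical tryptase genes TPSAB1 (0.70 ± 0.17) and TPSB2 (0.61 ± 0.15), whose reads the counting could split (camera adjusted p = 3.4e-04, and adjusted p = 0.317 with an estimated correlation). With a participant left out, TPSAB1 kept its call in 5 of 8 edgeR fits (0.59 to 0.84) and TPSB2 in 6 (0.48 to 0.69).

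In the list of progenitors and fibroblasts (camera adjusted p = 0.498 before weight loss and 0.318 after it), SEMA3C was higher in SFAT at both visits (0.70 ± 0.11 and 0.66 ± 0.09), and the complement gene C7 lower after weight loss (-1.36 ± 0.12). The list of Schwann cells and nerve was called lower by camera (adjusted p = 0.0459 before weight loss and 0.0014 after it), but not with an estimated correlation (adjusted p = 0.292 and 0.271). Its neural adhesion gene NCAM1 was lower at both visits (-0.74 ± 0.14 and -1.08 ± 0.17). Cytokines, chemokines and acute-phase genes were higher in SFAT before weight loss for 5 and lower for 1 of 34 (10 and 1 adjusted over the list alone, and 6 higher without the shallow pair), with the chemokine CXCL8 at 1.61 ± 0.35 and IL10 at 1.17 ± 0.28, at levels of 1.47 ± 1.07 and 2.28 ± 1.30 CPM in SFAT (SD, n = 9; camera adjusted p = 3.9e-06, and adjusted p = 0.357 with an estimated correlation). In the skin epithelium list (camera adjusted p = 0.567) the keratin KRT14 was higher (1.44 ± 0.33) and the plakophilin PKP1 lower (-0.74 ± 0.16). With a participant left out, IL10 kept its call in 5 of 9 edgeR fits (1.04 to 1.35) and PKP1 in 7 (-0.85 to -0.65).

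Macrophage genes were higher in SFAT at both visits, with 10 and 18 of them called higher without the shallow libraries and their partners. A lower share of adipocytes in SFAT would raise all other cell types alike. The macrophage list exceeded the blood endothelium list by 0.76 ± 0.56 before weight loss (SD, n = 9, exact sign-flip permutation test, p = 0.0039) and by 0.75 ± 0.28 after it (n = 8, exact sign-flip permutation p = 0.0078). These lists had already been seen to move in opposite directions in the same pairs, so the p-values add no separate evidence. The endothelium list was itself lower in SFAT and is no neutral gauge. Adipocyte identity genes showed no fall in SFAT, at -0.0030 ± 0.14 before weight loss (SD, n = 9) and 0.0015 ± 0.25 after it (n = 8). Before weight loss the progenitor (0.06 ± 0.23) and smooth muscle lists (-0.11 ± 0.26) showed no clear rise, while matrix (0.22 ± 0.15) and T and NK cells (0.46 ± 0.57) were higher. Other cell types thus did not all rise alike, but a lower adipocyte share as part of the difference is left open. Blood left in the biopsies would leave out genes that blood monocytes carry little of, such as C1QC, yet these differed by 0.34 ± 0.40 before (6 of 9 participants, exact sign-flip permutation p = 0.0469) and 0.47 ± 0.15 after (8 of 8, p = 0.0078). These genes belong to the macrophage list, already seen to be higher in the same pairs, so the p-values add no separate evidence. The red blood cell list was also higher in SFAT after weight loss (camera adjusted p = 0.0214, and adjusted p = 0.365 with an estimated correlation). Blood as a source of part or all of the difference is thus left open. More macrophages in thigh fat, more RNA of these genes per macrophage, and a difference in where or how the tissue was sampled may each account for it, and none of these was tested.

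Fatty acid and triglyceride synthesis genes ranked lower by camera after weight loss in both depots, but not with an estimated correlation (camera adjusted p = 0.243 in SAAT and 0.251 in SFAT). If a lower share of adipocytes were the cause, adipocyte identity genes would fall by as much. In SAAT the synthesis list lay lower, by -0.17 ± 0.14 relative to identity genes (SD, n = 8, exact sign-flip permutation test, p = 0.0156, 7 of 8 participants). In SFAT the difference was -0.12 ± 0.14 (p = 0.0703, exact sign-flip permutation test). The comparison was chosen after the fall of the synthesis list was seen in these same pairs. Its p-values are thus no separate evidence, and a lower adipocyte share is left open in both depots. Without the shallow libraries the list's mean log2 change was -0.24 in SAAT and -0.21 in SFAT. A response of adipocytes to lower energy intake may underlie the pattern, as may the diet at the time of biopsy, and neither was tested.

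The macrophage gene CD68 (chromosome 17, 7579467 to 7582113, GRCh38) averaged 0.254 ± 0.261 CPM over all 34 libraries, while CD14 averaged 53.1 ± 17.6 and CD163 91.2 ± 32.6. In the annotation used here 81.7% of the exon bases of CD68 lie in exons of other genes on the same strand. Of 560 coding genes with at least 80% such overlap, 7.5% reached a mean of 1 CPM, against 63.7% of 11021 without overlap (Fisher's exact test across genes, p = 4.0e-165). Of 35 genes overlapped on the opposite strand alone, 14 reached it. A candidate explanation is that reads assigned to more than 1 gene were left uncounted, so levels of CD68 and of genes like it could be far too low.

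A shrinking depot difference with weight loss was tested as a hypothesis. In genes called between depots without the participant being measured (945 to 1811 genes), the mean signed log2 difference was 0.51 ± 0.14 before and 0.53 ± 0.16 after (SD, n = 8). The change of 0.0170 ± 0.16 (exact sign-flip permutation test, p = 0.773) gave no sign of shrinkage, and the difference was smaller after weight loss in 5 of 8 participants.

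Labels were also swapped within participants to ask how often such swaps give as many calls. For the depots before weight loss 1 of 100 draws, the real one, gave as many as 1604 calls, the highest other giving 227, and for the depots after it 1 of 100 gave 1413, the highest other 245. For weight loss in SFAT 1 of 100 gave 11, the highest other 8. In these 3 comparisons as many calls were thus rare under swapped labels, though 100 draws cannot show a share below 1 in 100. The SFAT count lay near that highest other draw and was fragile, at 1 to 9 with a participant left out. For weight loss in SAAT 8 of 100 draws gave at least 1 call, the highest other 2, so chance cannot be excluded for that count. For the interaction, with 0 calls, any draw gives as many (40 of 40), with 7 other draws above 0, a median of 0 and a highest of 17, so the count supports nothing here.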
